A study of Mus musculus with 6 samples.

How the data were processed

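Total RNA from whole pancreatic islets of 14-week-old mice was sequenced in 6 libraries, 3 from control mice with floxed Ssbp3 alleles and 3 from littermates that carried floxed Ssbp3 together with MIP-CreER, per the labels. The labels do not say whether a library holds the islets of a single animal or of a pool, so p-values measure the spread between these libraries, part of which may be technical. Per the submitters' processing notes, FastQC 0.11.9, Trim Galore 0.6.7, STAR 2.7.3a and featureCounts were used with the mouse genome build GRCm39 (mm39). The annotation release, the strand setting and the treatment of read pairs and of multi-mapping reads are not given in the sources used here. The authors deposited a table of unnormalized whole-number counts for 56980 Ensembl gene IDs. Between 62.3% and 73.2% of the nonzero counts in a library were even, a share that arises when both reads of a pair are counted separately, so a count may stand for less than a whole fragment.

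The names of the 6 count columns give the group of each library but not which animal it was, so libraries are called control 1 to 3 and knockout 1 to 3 after the columns. Symbols were matched by gene ID for 52073 of the 56980 IDs. IDs without a symbol took 2.20% to 5.33% of the counts of a library, and a single such ID took 1.68% to 4.40%. Those IDs stayed in the library sizes and in the test over all genes. The annotation at hand belongs to another genome build, so no coordinates are given, and transcript length and GC content were taken from it by gene ID for 97.6% of the genes tested. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and counts of near-identical gene copies are uncertain.

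Library totals ranged from 14907641 to 225428920 counts, and each group held 1 shallow library, control 1 with 17587055 counts and knockout 1 with 14907641. A count of 3, taken as the floor, corresponded to 0.0135 CPM in the deepest and 0.194 CPM in the shallowest library. Such floors and the 95% counting interval given for Alox15 cover counting error only, since reads are not independent molecules. Libraries of the same group had Pearson correlations of log2 CPM across genes between 0.946 and 0.977. Pairs across the groups ran from 0.9055 to 0.9708, so the 2 ranges overlapped. Genes are not independent replicates in these values. The counts of no same-group pair agreed within sampling noise (mean chi-square per gene of 40.2 or more), so all 6 libraries were kept as separate samples.

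Genes were tested in R 4.3.3 with edgeR 4.0.16: genes with low counts were removed by filterByExpr, libraries were scaled by TMM factors, and the quasi-likelihood test with robust shrinkage compared knockout with control. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 18558 genes tested are called. Log2 fold changes are knockout over control, with the standard error (SE) derived from the test. CPM values use the TMM-scaled library sizes. On counts simulated from the means and depths of these libraries with 194 of 18053 tested genes changed, the same test called 5.88% of 68 genes changed 1.5-fold, 50.7% of 69 changed 2-fold and 77.2% of 57 changed 4-fold. It called 0.0728% of the 17859 unchanged genes in that simulation, beside 83 changed genes. False calls were thus a larger share of its calls than the threshold of 0.05 names.

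Before the data were examined, 25 gene lists and the rule for naming genes were fixed. The lists were mature beta cells, partners of LDB1 and SSBP3, genes named in earlier islet work as ISL1 or LDB1 targets, genes normally kept low in islets, dedifferentiation, alpha cells, delta, PP and epsilon cells, acinar cells, duct cells, endothelial cells, stromal cells, immune cells and Schwann cells. Further lists were genes that respond to growth hormone or prolactin receptor signalling, exocytosis, secretory granules, cell adhesion, the unfolded protein response, oxidative phosphorylation, glycolysis, glucose response through ChREBP, the cell cycle, interferon response, early response to tissue handling, and sex-linked genes. The sex-linked list was read per library, and the other 24 were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the 24 lists, with fry and an estimated correlation beside it. The naming rule took Ssbp3, 11 islet genes fixed in advance, and the 8 largest increases and 8 largest decreases among called genes. Those 16 had to reach a mean of at least 5 CPM in a group, show no overlap between groups, carry a proper symbol and lie outside the acinar list. It also took up to 4 members with the smallest p of each list. Other genes named were chosen after their values were seen. Some genes that the rule took are not reported here.

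Alternatives planned in advance were DESeq2's size factors and upper-quartile factors in edgeR, hormone and acinar genes left out of the library sizes, no filter or a filter of 1 CPM, DESeq2 1.42.0, limma-voom, non-robust shrinkage, a test against a 1.2-fold change, the acinar level as a covariate, and leaving out each library in turn. After seeing the data, fits without the 2 shallow libraries, with depth class as a covariate, with every library thinned to the smallest total, with counts halved, with the column number as a block, and with offsets for transcript length and GC content were added. All 10 ways of splitting the 6 libraries into groups of 3 were tested.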

Results

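The data were gene counts from whole pancreatic islets, the clusters of endocrine cells in which beta cells make insulin. The 3 control libraries came from 14-week-old mice with floxed alleles of Ssbp3, which encodes a co-regulator that binds the LIM-domain cofactor LDB1. The 3 knockout libraries came from littermates that also carried MIP-CreER, a tamoxifen-inducible Cre recombinase under the mouse insulin promoter. The comparison addresses how loss of SSBP3 alters islet gene expression, with beta-cell identity and islet architecture among the interests named for the series. Library totals were 17587055, 89044012 and 225428920 counts for control 1, 2 and 3, and 14907641, 83647474 and 93841878 counts for knockout 1, 2 and 3. No libraries with MIP-CreER and intact Ssbp3 were analysed here, so the transgene and the knockout differ together between the groups. Whether, when and in which group tamoxifen was given is not reported here, and its effect was not tested.

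Ssbp3 (ENSMUSG00000061887) measured 65.8, 81.3 and 74.2 CPM in control 1, 2 and 3 and 52.3, 58.1 and 57.1 CPM in knockout 1, 2 and 3. Every knockout library lay below every control library, but with a log2 fold change of -0.40 (SE 0.117) the gene was not called (edgeR adjusted p = 0.0581). The deleted part of the gene is not given in the sources used here, and the counts cover the whole gene and all islet cells, so they do not measure recombination in beta cells. Over 22 alternatives its adjusted p ran from 0.0135 to 0.328. In the same islets Mafa, a transcription factor of mature beta cells, fell 2.21-fold, and the glucose-6-phosphatase gene G6pc2 fell 2.32-fold. Tph1, which makes the enzyme of the first step of serotonin synthesis, rose from 0.0655 ± 0.0625 to 8.66 ± 2.71 CPM, and the noncoding RNA Meg3 fell from 151 ± 29.3 to 10.2 ± 2.81 CPM (mean ± SD, n = 3 per group). Lists of mature beta-cell genes, endoplasmic reticulum (ER) chaperones and oxidative phosphorylation subunits fell, while lists of growth hormone and prolactin response, dedifferentiation, cell adhesion and glucose response rose by camera with its preset correlation. With an estimated correlation camera passed 0 of 24 lists (lowest adjusted p = 0.466; 2 at an unadjusted p under 0.05).

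**Figure D1:**
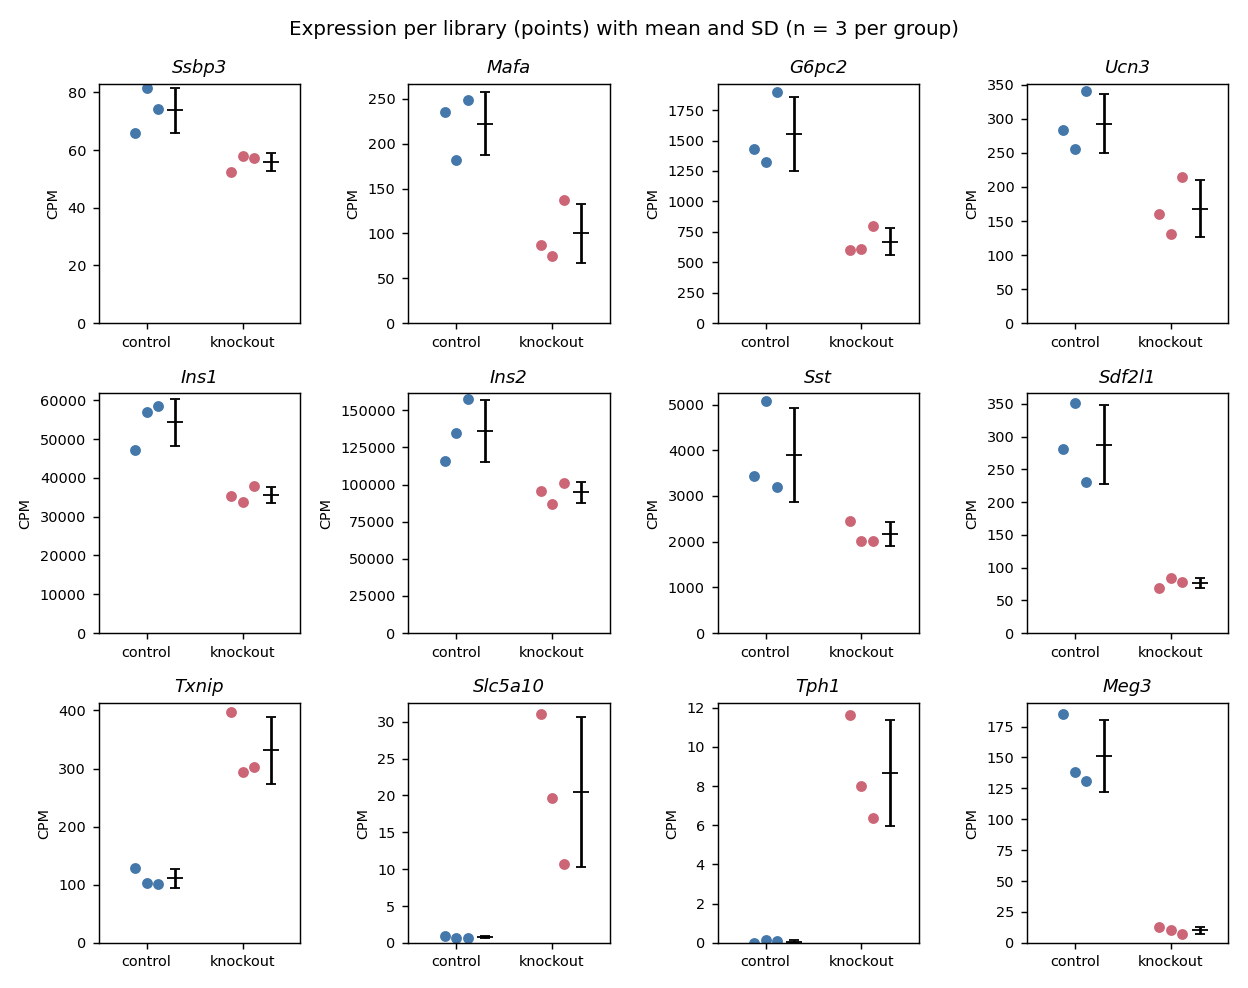
Expression of 12 genes in CPM (vertical axes, linear and starting at 0) in each control (blue) and knockout (red) library, with mean and SD beside the points (n = 3 per group). Mafa, G6pc2, Ucn3, Sst, Sdf2l1 and Meg3 were called lower and Txnip, Slc5a10 and Tph1 higher, while Ssbp3, Ins1 and Ins2 were not called although no library of either group overlapped the other.

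Of 18558 genes tested, 1312 were called by edgeR, 691 higher and 621 lower in knockout islets, and 4014 had an unadjusted p under 0.05. More than 2-fold changes were called for 236 higher and 164 lower genes. Each called gene separated the groups without overlap, as did 28.1% of all genes tested against 10% by chance. Upper-quartile scaling gave 613 higher and 829 lower genes, a share of 42.5% higher against 52.7%. Leaving out control 1, control 2 or knockout 1 gave 661, 519 and 610 called genes, and the lower genes numbered 400 without knockout 2. Without control 1 and knockout 1, the shallowest library of each group, an alternative added after seeing the data, 124 genes were called. Of the 63 called genes that the naming rule took, 37 kept their call whichever library was left out, and 26 kept it without both shallow libraries.

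Log2 fold changes were higher for longer transcripts, with a Spearman's rho of 0.244 across 18113 genes, which are not independent replicates, and a rho of 0.0065 with GC content. A set of 12 noncoding RNAs of the nucleus, listed after Neat1 and Meg3 had been seen and before the values of the 12 were, had a median log2 fold change of -1.24, and 4 of them fell. Among these, Malat1 fell from 116 ± 46.6 to 26.1 ± 8.32 CPM (edgeR adjusted p = 0.0297), with the call lost without control 2, knockout 2 or knockout 3 (adjusted p 0.121, 0.117 and 0.105; 1.40e-05 to 0.121 over 22 alternatives). Malat1 was singled out after its value was seen. Transcripts of Ins1 and Ins2 took 18.3% ± 2.60 of the counts in control and 13.6% ± 2.03 in knockout libraries (SD, n = 3). The acinar list took 5.03% ± 1.52 and 5.84% ± 3.18, and mitochondrially encoded transcripts 1.92% ± 0.404 and 1.72% ± 0.194, both with overlap between the groups. Of 18 mitochondrially encoded genes tested, 3 fell and 0 rose by edgeR, and these 3 were named after their values were seen. The ribosomal RNA genes mt-Rnr2 and mt-Rnr1 fell from 1007 ± 201 to 557 ± 43.2 CPM and from 241 ± 43.2 to 161 ± 17.9 CPM (log2 fold change -0.85 and -0.58, edgeR adjusted p 0.00694 and 0.0284), and mt-Nd2, a subunit of respiratory complex I, from 1206 ± 221 to 801 ± 53.6 CPM (-0.59, 0.0398). The call of mt-Rnr2 was lost without knockout 1 (0.0502), and that of mt-Rnr1 without control 1, knockout 1 or knockout 3 (0.112, 0.0838 and 0.0609). That of mt-Nd2 was lost without control 1, control 3, knockout 1, knockout 2 or knockout 3 (0.118, 0.0994, 0.0989, 0.126 and 0.0779). All 3 calls were lost without both shallow libraries, and with length and GC offsets mt-Rnr1 and mt-Nd2 had log2 fold changes of -0.20 and -0.23 and were not called. Over 22 alternatives the adjusted p ran from 2.90e-07 to 0.158 for mt-Rnr2, 0.000824 to 0.301 for mt-Rnr1 and 0.00138 to 0.440 for mt-Nd2.

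**Figure D2:**
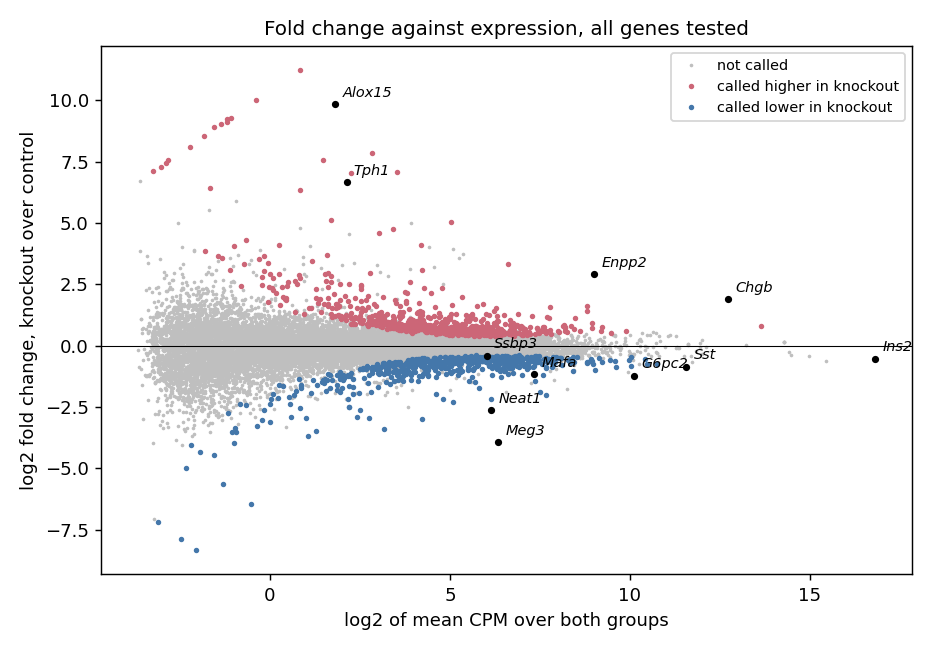
Log2 fold change of knockout over control (vertical axis) against log2 of the mean CPM over both groups (horizontal axis) for the 18558 genes tested, each point a gene, with the 691 genes called higher in red and the 621 called lower in blue. Alox15 and Tph1 lie far above 0, Meg3 and Neat1 far below, and Chgb and Enpp2 are abundant genes called higher.

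Genes of mature beta cells fell as a list. Of its 25 members tested, 6 fell and 1 rose, against 9 and 2 when adjusted over the list alone, with a median log2 fold change of -0.31 (camera adjusted p = 0.00574). With an estimated correlation the adjusted p was 0.746, with length and GC offsets the median was -0.19, and without control 3 or knockout 2 the adjusted p was 0.0536 and 0.1001 (0.000111 to 0.746 over 18 alternatives). The list did not pass with fry for a common direction (adjusted p = 0.205). G6pc2 (ENSMUSG00000005232), which opposes glucokinase in beta cells, fell from 1553 ± 305 to 669 ± 112 CPM, a log2 fold change of -1.22 (SE 0.176, edgeR adjusted p = 0.00175). Mafa (ENSMUSG00000047591) fell from 222 ± 35.2 to 100.2 ± 33.0 CPM, a log2 fold change of -1.15 (SE 0.220, edgeR adjusted p = 0.0156). Pcsk1, a prohormone convertase, fell by 0.68 on the log2 scale (edgeR adjusted p = 0.0105), and Gipr, the receptor of the incretin GIP, fell by 1.03 (edgeR adjusted p = 0.0133). Rfx6, a transcription factor of endocrine cells, was the member that rose (log2 fold change 0.51, edgeR adjusted p = 0.0338). The edgeR calls of Mafa ended without control 1, control 3 or knockout 1 (adjusted p 0.0607, 0.0625 and 0.0611), of Pcsk1 without knockout 1 or 2 (0.0697 and 0.0549), of Gipr without control 1 (0.0545), and of Rfx6 without control 1, control 2, knockout 1 or knockout 3 (0.0586, 0.172, 0.102 and 0.0739). Over 22 alternatives the adjusted p ran from 5.06e-14 to 0.174 for Mafa, 6.37e-05 to 0.183 for Pcsk1, 8.54e-06 to 0.118 for Gipr and 0.00456 to 0.173 for Rfx6, which was chosen after its value was seen. Mafa was also not called with length and GC offsets (adjusted p = 0.0763, log2 fold change -1.24). G6pc2 lost its edgeR call only without both shallow libraries (adjusted p = 0.105), where Mafa, Pcsk1, Gipr and Rfx6 were not called either.

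The insulin genes were lower in all 3 knockout libraries without passing the edgeR test. Ins1 measured 54310 ± 6116 CPM in control and 35653 ± 2032 CPM in knockout islets, a log2 fold change of -0.61 (SE 0.212, edgeR adjusted p = 0.109), and Ins2 had a log2 fold change of -0.52 (SE 0.243, adjusted p = 0.234). Both were called lower by DESeq2, without a filter and with the acinar covariate, and Ins1 also by limma-voom (4 and 3 of 22 alternatives, adjusted p 0.000159 to 0.370 for Ins1 and 0.00596 to 0.505 for Ins2). Reads can be shared between these paralogs. Pdx1, a transcription factor of beta cells, had a log2 fold change of -0.38 (edgeR adjusted p = 0.0888), and was called without knockout 3 (adjusted p = 0.0224; 0.0197 to 0.412 over 22 alternatives). The glucose transporter gene Slc2a2 (log2 fold change -0.61, adjusted p = 0.343) and the incretin receptor gene Glp1r (0.53, adjusted p = 0.178) were not called by edgeR. They were called in 2 and 3 of 22 alternatives, both of them with the acinar covariate, with ranges of 0.0166 to 0.638 and 0.00184 to 0.473.

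Genes named in earlier islet work as targets of ISL1 or LDB1 fell as a list, with 4 of 14 members lower and none higher, 6 and 0 when adjusted over the list alone. The median log2 fold change was -0.48 (camera adjusted p = 0.00129), the adjusted p = 0.698 with an estimated correlation (5.67e-05 to 0.698 over 18 alternatives), and the median was -0.37 with length and GC offsets. Fry for a common direction did not pass the list (adjusted p = 0.108). All 14 members stand on another list and 10 of them on the beta-cell list. Apart from Mafa and G6pc2, the members that fell were Ucn3 (ENSMUSG00000044988), a peptide hormone gene of mature beta cells (from 293 ± 43.8 to 168 ± 42.4 CPM, edgeR adjusted p = 0.0176), and Sst. Ucn3 lost its edgeR call without control 1, knockout 1 or knockout 2 (adjusted p 0.0613, 0.0809 and 0.0548) and with length and GC offsets (6.93e-07 to 0.218 over 22 alternatives).

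Among partners of LDB1 and SSBP3, Lmo1, a LIM-only protein gene, fell from 11.1 ± 2.32 to 2.93 ± 1.18 CPM (log2 fold change -1.89, edgeR adjusted p = 0.00207). Bcl9 rose from 24.4 ± 3.71 to 41.5 ± 8.73 CPM (edgeR adjusted p = 0.0164), with the call lost without control 1 or control 2 (adjusted p 0.0805 and 0.0824; 1.98e-05 to 0.135 over 22 alternatives). The other 16 of 18 members tested were not called (3 higher and 2 lower when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.659). Ldb1 had a log2 fold change of 0.42 (edgeR adjusted p = 0.0679), Ssbp4 of 0.44 (0.0618) and Isl1, a LIM-homeodomain factor, of -0.15 (0.501). Ldb1 and Ssbp4 were called without knockout 3 (adjusted p 0.0317 and 0.0190), with ranges over 22 alternatives of 0.0260 to 0.364 and 0.00874 to 0.381.

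Dedifferentiation genes rose as a list, with 5 of 20 members higher and none lower, against 9 and 1 when adjusted over the list alone. The median log2 fold change was 0.39 (camera adjusted p = 0.0189), the adjusted p = 0.698 with an estimated correlation and 0.144 without control 3 (0.000563 to 0.698 over 18 alternatives). With fry for a common direction the list did not pass (adjusted p = 0.109). Slc5a10 (ENSMUSG00000042371), a sugar transporter gene, rose from 0.780 ± 0.158 to 20.4 ± 10.1 CPM (log2 fold change 4.77, SE 0.394, edgeR adjusted p = 0.000138). Gast, which encodes gastrin, rose from 0.413 ± 0.210 to 3.13 ± 1.68 CPM (edgeR adjusted p = 0.00724), and Neurog3, the transcription factor of endocrine progenitors, from 3.59 ± 0.327 to 7.57 ± 2.03 CPM (0.0228). Aldh1a3, a retinaldehyde dehydrogenase gene, rose from 9.76 ± 4.01 to 26.4 ± 8.25 CPM (edgeR adjusted p = 0.0343). Neurog3 lost its edgeR call without control 1, control 2, knockout 1 or knockout 2 (adjusted p 0.0567, 0.0962, 0.0862 and 0.0543), and Aldh1a3 without control 3, knockout 1 or knockout 3 (0.128, 0.0947 and 0.0676). Their ranges over 22 alternatives were 0.00131 to 0.152 and 3.16e-12 to 0.145. Gast lost its edgeR call only without both shallow libraries (adjusted p = 0.107). Of 27 genes normally kept low in islets, Tgm2 rose from 9.64 ± 0.718 to 18.9 ± 2.25 CPM (edgeR adjusted p = 0.00370), a call lost only without both shallow libraries (0.0832). No other of the 27 was called by edgeR, while 3 had an unadjusted p under 0.05, DESeq2 called 3 and limma-voom 1. That list did not pass (camera adjusted p = 0.609), and Ldha, lactate dehydrogenase A, had a log2 fold change of -0.73 (edgeR adjusted p = 0.218, called without control 1 at 0.0183; 0.00351 to 0.555 over 22 alternatives).

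The list of growth hormone and prolactin receptor response had 7 of its 11 members higher and none lower, before and after adjusting over the list alone. Its median log2 fold change was 1.02 (camera adjusted p = 1.79e-05), the adjusted p = 0.466 with an estimated correlation (3.32e-07 to 0.466 over 18 alternatives), and 2 members stand on other lists. Tph1 (ENSMUSG00000040046) rose by a log2 fold change of 6.68 (SE 0.464, edgeR adjusted p = 7.86e-06), and its neuronal counterpart Tph2 by 1.96 (0.00175). The call of Tph2 was lost only without both shallow libraries (edgeR adjusted p = 0.0566). The STAT5 feedback genes Cish (from 16.4 ± 1.18 to 64.0 ± 12.6 CPM, edgeR adjusted p = 2.34e-05) and Socs2 (from 26.8 ± 2.50 to 81.4 ± 19.7 CPM, 0.000164) rose as well. Ivd, an enzyme of leucine breakdown, rose from 52.5 ± 1.26 to 107 ± 17.2 CPM (edgeR adjusted p = 0.000581). The prolactin receptor gene Prlr was not called (log2 fold change -0.34, edgeR adjusted p = 0.198).

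ER chaperone and unfolded protein response genes fell as a list, with 10 of 22 members lower and none higher, 12 and 0 when adjusted over the list alone. The median log2 fold change was -0.40 (camera adjusted p = 2.71e-06), the adjusted p = 0.466 with an estimated correlation (1.73e-06 to 0.466 over 18 alternatives), and the median was also -0.40 with length and GC offsets. Sdf2l1 (ENSMUSG00000022769) fell from 288 ± 60.5 to 76.8 ± 7.70 CPM (log2 fold change -1.90, SE 0.156, edgeR adjusted p = 2.93e-05). Creld2 fell from 179 ± 32.9 to 78.1 ± 3.17 CPM, Manf from 462 ± 47.8 to 225.2 ± 17.0 CPM and the protein disulfide isomerase gene Pdia6 from 702 ± 95.8 to 350.0 ± 3.66 CPM, with edgeR adjusted p of 0.000346, 0.000531 and 0.000961. The calls of Creld2, Manf and Pdia6 were lost only without both shallow libraries (edgeR adjusted p 0.0566, 0.0626 and 0.0803). Hspa5, the chaperone BiP, fell from 2155 ± 108 to 1294 ± 62.3 CPM (edgeR adjusted p = 0.00847), with the call lost without knockout 1 (adjusted p = 0.0623; 3.32e-08 to 0.165 over 22 alternatives); it was chosen after its value was seen.

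Nuclear-encoded subunits of oxidative phosphorylation fell as a list, with 17 of 39 lower and none higher, 23 and 0 when adjusted over the list alone. The median log2 fold change was -0.39 (camera adjusted p = 6.21e-10), the adjusted p = 0.551 with an estimated correlation (3.54e-10 to 0.551 over 18 alternatives), and the median was -0.27 with length and GC offsets. Uqcrb fell by 0.83, Cox6c by 0.83, Uqcrq by 0.79 and Ndufa4 by 0.66 on the log2 scale, with edgeR adjusted p of 0.00202, 0.00235, 0.00354 and 0.00921. Each of these calls was lost only without both shallow libraries (edgeR adjusted p 0.0694, 0.0889, 0.0967 and 0.128). Genes induced by glucose through ChREBP rose as a list, 3 of 13 higher and none lower, 6 and 0 when adjusted over the list alone (median log2 fold change 0.34, camera adjusted p = 0.0126). The adjusted p = 0.515 with an estimated correlation and 0.0768 with length and GC offsets, where the median was 0.11 (2.66e-05 to 0.515 over 18 alternatives). Txnip (ENSMUSG00000038393), an arrestin-family gene that responds to glucose, rose from 111 ± 16.0 to 331 ± 57.3 CPM (log2 fold change 1.58, edgeR adjusted p = 0.000105), and its relative Arrdc4 from 14.8 ± 1.22 to 37.3 ± 0.830 CPM (0.000127). The liver-type pyruvate kinase gene Pklr rose from 6.24 ± 2.84 to 21.3 ± 3.87 CPM (edgeR adjusted p = 0.0124; 0.0656 without knockout 3; 7.02e-16 to 0.0656 over 22 alternatives). Of 18 glycolysis genes 2 were higher, Pklr among them, and none lower (2 and 3 when adjusted over the list alone). The glycolysis list did not pass (median log2 fold change -0.38, mean -0.002, camera adjusted p = 0.229), but passed as lower without control 1 and without both shallow libraries (adjusted p 0.00834 and 0.0177; 0.00834 to 0.897 over 18 alternatives).

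Secretory granule genes moved in both directions. Of 18 members 4 rose and 2 fell (6 and 5 when adjusted over the list alone), with a median log2 fold change of 0.03 and a camera adjusted p of 0.763. Chgb (ENSMUSG00000027350), which encodes the granule protein chromogranin B, rose from 2838 ± 704 to 10642 ± 2361 CPM (log2 fold change 1.91, SE 0.235, edgeR adjusted p = 0.000538), and the carboxypeptidase gene Cpd rose from 53.4 ± 3.17 to 107 ± 22.6 CPM (0.00154). The calls of Chgb and Cpd were lost only without both shallow libraries (edgeR adjusted p 0.0776 and 0.0689). Chga, which encodes chromogranin A, rose from 9360 ± 1041 to 16181 ± 3164 CPM (edgeR adjusted p = 0.0352). Its call ended without control 1, control 2, knockout 1 or knockout 2 (adjusted p 0.163, 0.0858, 0.163 and 0.0730; 1.84e-05 to 0.375 over 22 alternatives). Of 25 exocytosis genes Cplx2 rose (log2 fold change 0.73, edgeR adjusted p = 0.0114) and Rab3a (-0.57, 0.0114) and Syt4 (-0.46, 0.0297) fell, against 1 higher and 3 lower when adjusted over the list alone. Their median log2 fold change was 0.02, their mean -0.04 and the camera adjusted p 0.659. Each of these 3 genes lost its edgeR call without some library. For Cplx2 these were control 1, control 2 and knockout 1 (adjusted p 0.0606, 0.0545 and 0.0629), and for Rab3a control 2 and knockout 2 (0.0538 and 0.0577). For Syt4 they were control 1, 2 and 3 and knockout 1 and 2 (0.0612, 0.0921, 0.0869, 0.112 and 0.135). Over 22 alternatives the ranges were 5.44e-06 to 0.193 for Cplx2, 0.00104 to 0.0904 for Rab3a and 0.00852 to 0.197 for Syt4.

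Cell adhesion and axon guidance genes rose as a list, with 6 of 27 higher and none lower, against 7 and 1 when adjusted over the list alone (median log2 fold change 0.35, camera adjusted p = 0.00698). The adjusted p = 0.466 with an estimated correlation and 0.0768 with length and GC offsets, where the median was 0.23 (2.66e-05 to 0.466 over 18 alternatives). Itga6, an integrin gene, rose from 38.9 ± 2.09 to 78.1 ± 8.52 CPM (edgeR adjusted p = 0.000442), and Ctnnb1, which encodes beta-catenin, from 268 ± 5.72 to 426 ± 52.2 CPM (0.00755). Ctnnb1 lost its call only without both shallow libraries (edgeR adjusted p = 0.0893). Cdh1, which encodes E-cadherin, rose from 250 ± 8.24 to 362 ± 39.9 CPM (edgeR adjusted p = 0.0200), and the ephrin gene Efna5 from 7.50 ± 2.37 to 14.5 ± 1.84 CPM (0.0254). The call of Cdh1 ended without control 1, control 2 or knockout 2 (adjusted p 0.0771, 0.0625 and 0.0769), and that of Efna5 without control 1, control 2 or knockout 1 (0.101, 0.117 and 0.0952), with ranges over 22 alternatives of 0.000686 to 0.124 and 0.000284 to 0.235.

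**Figure D3:**
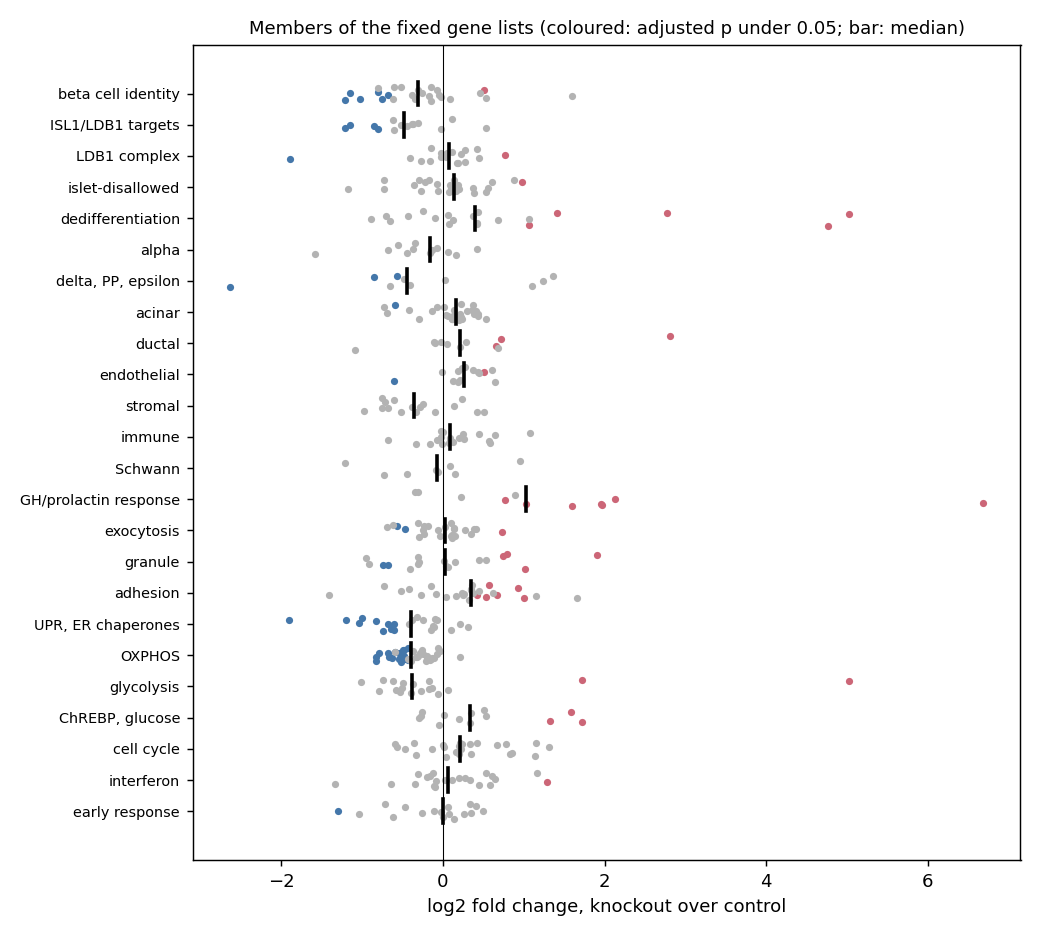
Log2 fold change of knockout over control (horizontal axis) for the tested members of 24 gene lists (vertical axis), each point a gene, coloured red if called higher and blue if called lower, with a black bar at the median of each list. The medians lie at 1.02 for growth hormone and prolactin response, -0.39 for oxidative phosphorylation and -0.31 for mature beta cells.

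Hormone genes of the other islet cells gave lower values as well. Sst (ENSMUSG00000004366), which encodes somatostatin of delta cells, fell from 3904 ± 1028 to 2163 ± 256 CPM (log2 fold change -0.85, SE 0.198, edgeR adjusted p = 0.0223). Ghrl, which encodes ghrelin, fell from 1.504 ± 0.717 to 0.2496 ± 0.119 CPM (edgeR adjusted p = 0.0288) and Rbp4 from 154 ± 36.2 to 104 ± 9.40 CPM (0.0477). Of the 10 members of the delta, PP and epsilon list these 3 fell and none rose (5 and 2 when adjusted over the list alone), and the list did not pass (median log2 fold change -0.44, camera adjusted p = 0.273). Gcg, the glucagon gene of alpha cells, had a log2 fold change of -0.36 (SE 0.219, edgeR adjusted p = 0.375), and Ppy of PP cells -0.65 (SE 0.231, adjusted p = 0.114; called without control 3 at 0.0185; 0.000636 to 0.350 over 22 alternatives). None of 13 alpha-cell genes was called by edgeR, 5 had an unadjusted p under 0.05, DESeq2 called 1, limma-voom called 0, and 1 higher and 3 lower passed when adjusted over the list alone. The alpha list did not pass (median -0.16, camera adjusted p = 0.209; 0.0454 without knockout 3; 0.0399 to 0.897 over 18 alternatives). The edgeR call of Sst ended without control 1, control 2, knockout 1 or knockout 2 (adjusted p 0.0545, 0.0880, 0.0629 and 0.0752), and that of Ghrl without the same libraries (0.0894, 0.164, 0.0611 and 0.0859). Rbp4 lost its call without any library except control 3 (adjusted p 0.123, 0.229, 0.0920, 0.112 and 0.116). The ranges were 1.33e-06 to 0.164 for Sst and 0.00129 to 0.229 for Rbp4 over 22 alternatives, and 0.00135 to 0.170 for Ghrl over the 20 that tested it.

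The largest increases among genes with at least 5 CPM in a group were in genes near the floor in control islets. Alox15, a lipoxygenase gene, had 2 counts over the 3 control libraries and 936 over the 3 knockout libraries, a ratio of 745 per unit of library size with a 95% counting interval (exact binomial) of 206 to 6157 (edgeR adjusted p = 0.000531). Both control counts came from control 3, and the knockout libraries measured 12.4, 6.49 and 2.12 CPM. The ratio was 1192 without knockout 3 and at least 152 without control 3, where 3 counts over the other control libraries stood in as the floor. Cldn8, a tight junction claudin gene, rose from 0.0535 ± 0.0640 to 14.3 ± 4.88 CPM, and Dnah8, an axonemal dynein gene, from 0.232 ± 0.146 to 22.9 ± 7.24 CPM, with edgeR adjusted p of 7.86e-06 and 3.19e-06. Malrd1 rose to 5.55 ± 1.58 CPM and the potassium channel gene Kcnj5 to 9.41 ± 1.13 CPM, from 0.0150 ± 0.0260 and 0.0391 ± 0.0677 CPM (edgeR adjusted p 3.60e-05 and 0.000211). Ighg2b, an immunoglobulin heavy chain gene of a family with similar sequences, rose from 0.281 ± 0.345 to 6.19 ± 2.62 CPM (edgeR adjusted p = 0.00952; 0.0536 without control 3; 1.59e-24 to 0.0536 over 22 alternatives).

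The largest decreases included noncoding RNAs. Meg3 (ENSMUSG00000021268), from the imprinted Dlk1-Dio3 region, fell by a log2 fold change of -3.92 (SE 0.219, edgeR adjusted p = 7.86e-06), and Mirg of the same region fell from 9.67 ± 1.06 to 1.69 ± 0.731 CPM (0.000346). Neat1, the RNA scaffold of nuclear paraspeckles, fell from 122 ± 12.9 to 19.6 ± 3.54 CPM (edgeR adjusted p = 3.03e-06), and Firre, also nuclear, from 16.6 ± 1.22 to 1.43 ± 1.16 CPM (0.00532). Protein-coding genes with large decreases were Dapl1 (from 33.4 ± 8.79 to 4.05 ± 0.933 CPM), Rgs11 (from 11.9 ± 4.11 to 1.63 ± 0.410 CPM) and the casein gene Csn3 (from 9.55 ± 3.89 to 1.196 ± 0.418 CPM), with edgeR adjusted p of 1.72e-05, 0.000152 and 0.000405. Xlr3b fell from 7.78 ± 2.29 to 1.35 ± 0.206 CPM (edgeR adjusted p = 0.000379), with counts that may be split among near-identical copies. These 8 genes, and Alox15, Cldn8, Malrd1, Dnah8, Kcnj5 and Tph1, kept their calls in every alternative run.

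Markers of cells outside the endocrine islet were called to unlike extents, with the largest share in the duct list. Of 30 acinar genes Bhlha15, a transcription factor gene, fell (log2 fold change -0.60, edgeR adjusted p = 0.00883; 0.0531 without knockout 1; 0.000485 to 0.1101 over 22 alternatives) and edgeR called no other, adjusted over all genes or over the list alone, with 1 called by DESeq2 and 1 by limma-voom. The acinar list had a median of 0.16 and a mean of 0.08 while camera gave the direction as lower (adjusted p = 0.763), and it passed as lower without knockout 2 (adjusted p = 0.00304) and as higher without knockout 3 (0.0322; 0.00304 to 0.978 over 18 alternatives). Of 11 duct genes 3 rose and none fell, among them Cftr, a chloride channel gene (from 0.223 ± 0.120 to 1.48 ± 0.463 CPM), and Ambp, against 3 and 1 when adjusted over the list alone (camera adjusted p = 0.273). Cftr and Ambp had edgeR adjusted p of 0.0169 and 0.0217. Spp1, which encodes osteopontin and was far more abundant, measured 1343.5 ± 167 CPM in control and 635 ± 251 CPM in knockout islets (log2 fold change -1.08, edgeR adjusted p = 0.0550), and was called lower in 11 of 22 alternatives, among them DESeq2 (0.000165), limma-voom (0.0265) and the fit without knockout 1 (0.0477). Cftr lost its call without control 2, knockout 1 or knockout 2 (0.0786, 0.0569 and 0.0514), and Ambp without control 1, control 3, knockout 1 or knockout 2 (0.0795, 0.0582, 0.0839 and 0.0592). Over 22 alternatives the ranges were 0.000111 to 0.10001 for Cftr, 0.000622 to 0.203 for Ambp and 2.11e-05 to 0.274 for Spp1. Of 14 endothelial genes Cdh5 rose (log2 fold change 0.51, edgeR adjusted p = 0.0481) and Egfl7 fell (-0.61, 0.0392), 2 and 1 when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.0744; 0.00458, higher, without knockout 1, and 0.00794 without both shallow libraries; 0.00458 to 0.806 over 18 alternatives). Cdh5 was not called without control 1, control 2, knockout 1 or knockout 2 (adjusted p 0.172, 0.159, 0.0786 and 0.167), nor Egfl7 without any library except control 3 (0.0930, 0.215, 0.0902, 0.0576 and 0.0922), with ranges over 22 alternatives of 0.00800 to 0.201 and 0.0105 to 0.215.

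None of 16 stromal, 20 immune and 8 Schwann cell genes was called by edgeR, over all genes or over the list alone. At an unadjusted p under 0.05 there was 1 gene in each of these lists, DESeq2 called 1 stromal, 1 immune and 0 Schwann genes, and limma-voom called 0 in all 3. Their camera adjusted p were 0.355, 0.473 and 0.377, with 0.00328 (lower) for the stromal list without control 3 and 0.0196 (higher) for the immune list without knockout 3 (0.00328 to 0.897 and 0.0196 to 0.943 over 18 alternatives). Of 25 cell cycle genes none was called by edgeR, over all genes or over the list alone, or by DESeq2 or limma-voom, and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.354; 0.0209, higher, without control 1, and 0.00248 without both shallow libraries; 0.00248 to 0.897 over 18 alternatives). Of 22 interferon-stimulated genes Gbp2 rose from 5.55 ± 1.11 to 13.5 ± 5.45 CPM (edgeR adjusted p = 0.0264) and edgeR called no other, adjusted over all genes or adjusted over the list alone (camera adjusted p = 0.495). At an unadjusted p under 0.05 there were 5 of them, and DESeq2 called 3 and limma-voom 0. Gbp2 was not called without control 1, 2 or 3 or knockout 1 or 2 (adjusted p 0.0673, 0.125, 0.0562, 0.0927 and 0.0685; 4.95e-07 to 0.187 over 22 alternatives). Of 17 early response genes Nr4a1, an orphan nuclear receptor gene, fell from 17.7 ± 4.29 to 7.14 ± 1.85 CPM (edgeR adjusted p = 0.00498), and 3 were lower when adjusted over the list alone (camera adjusted p = 0.659). Nr4a1 lost its call only without both shallow libraries (edgeR adjusted p = 0.0722). The Y-linked gene Ddx3y measured between 22.2 and 33.7 CPM in every library and Xist at most 2.48 CPM.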

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

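The fits without the 2 shallow libraries, with depth class as a covariate, with thinned or halved counts, with the column number as a block and with length and GC offsets were chosen after seeing the data. No paired analysis was possible because the labels' numbers for the 2 groups share a single value, and the numbers 1 to 3 in the column names are not tied to animals by the labels. Columns with the same number deviated from their group means with correlations of 0.0162, 0.0806 and 0.0659 across genes, each the highest for its library but small. Library totals rose with the column number in both groups, so these values cannot tell pairing from depth. Deviations within a group also sum to 0, so the correlations are not independent of each other. With the column number as a replicate block, 2105 genes were called (1118 higher, 987 lower), 1279 of them among the 1312 called without it, Ssbp3 passed the threshold (log2 fold change -0.40, adjusted p = 0.0202), as did Ppy, Pdx1, Slc2a2, Glp1r, Ssbp4 and Spp1, and of the calls named here that of Ghrl ended (adjusted p = 0.0525). The count of called genes, 1312 with edgeR, lay within 1.5 times that number in 14 of 22 alternatives. It was 2153 (1222 higher) without a filter, where more genes were tested, 2094 (1107 higher, 987 lower) with DESeq2, and 519 (286 higher, 233 lower) against a 1.2-fold change, a stricter test. With the acinar covariate 1038 genes were higher, and the cause was not tested. Leaving out a library gave 519 to 1309 called genes, 295 to 719 higher and 224 to 590 lower, and leaving out both shallow libraries gave 124 (76 higher, 48 lower), where fewer samples remained. Of the 124 genes, 120 were among the 1312. Ssbp3 passed the threshold with upper-quartile factors (log2 fold change -0.45), the 1 CPM filter (-0.41), DESeq2 (-0.39), the acinar covariate (-0.40), thinning (-0.44) and length and GC offsets (-0.42), with an adjusted p between 0.0135 and 0.328 over the 22 alternatives; the cause was not tested. Of the 24 lists, 8 passed with the preset correlation, 0 with an estimated correlation (2 at an unadjusted p under 0.05), 5 with fry for a common direction and 13 with fry for either direction. The beta-cell, ISL1 or LDB1 target and dedifferentiation lists passed with the preset correlation but not with fry for a common direction (adjusted p 0.205, 0.108 and 0.109). The acinar list passed as higher without knockout 3 (adjusted p = 0.0322), and its adjusted p ran from 0.00304 to 0.933 when a library was left out; the cause was not tested. Over all alternatives, adjusted p ran from 5.06e-14 to 0.174 for Mafa, 1.33e-06 to 0.164 for Sst and 0.000111 to 0.746 for the beta-cell list. For named genes the alternatives gave 2729 values on the same side of the threshold, 254 calls lost and 125 gained, and for lists 396, 16 and 19. Simulated 1.5-fold changes were called in 5.88% of 68 genes where 194 of 18053 genes changed, a setting with fewer calls and so a stricter adjusted threshold than in these data; the share missed in these data was not measured.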

Other observations

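The tests of nuclear RNAs, imprinted genes, shallow libraries, islet hormones and transcript length, and the genes and gene sets named first below, were chosen after the results were seen; those of splits, growth hormone response and acinar carry-over were set before. Genes of protein entry into the ER and of the first steps of N-glycosylation were lower beside the ER chaperones. All 26 of a set of translocon, signal peptidase and oligosaccharyltransferase genes had log2 fold changes below 0, and 17 fell (median -0.61, -0.56 with length and GC offsets). The set had a camera p of 2.15e-14 with the preset and 0.0140 with an estimated correlation, but it was written after some of its members had been seen to fall. Sec61b fell from 264 ± 46.1 to 144 ± 16.3 CPM, Ostc from 297 ± 24.8 to 164 ± 6.00 CPM and the signal peptidase gene Spcs1 from 207 ± 25.3 to 118 ± 4.02 CPM (edgeR adjusted p 0.00372, 0.000963 and 0.00202), calls that were lost of the 22 alternatives only without the 2 shallow libraries.

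Several abundant genes outside the fixed lists also changed. Enpp2, which encodes the secreted enzyme autotaxin, rose from 121 ± 9.53 to 913 ± 137 CPM (log2 fold change 2.91, SE 0.150, edgeR adjusted p = 1.76e-06), the smallest p of all genes tested. Selenop, a secreted selenoprotein gene, rose from 222 ± 15.6 to 674 ± 58.9 CPM and the signalling ligand gene Wnt4 from 248 ± 6.81 to 652 ± 110 CPM (edgeR adjusted p 2.34e-05 and 0.000148). Pdyn, which encodes the opioid precursor prodynorphin, fell from 323 ± 112 to 80.1 ± 28.8 CPM (edgeR adjusted p = 0.0317), a call lost without control 2, knockout 2 or knockout 3 (adjusted p 0.159, 0.122 and 0.0888; 2.23e-05 to 0.159 over 22 alternatives). Enpp2, Selenop and Wnt4 kept their calls in every alternative run.

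Of the 10 splits of the 6 libraries into groups of 3, 1, the real one, gave as many as 1312 called genes, the highest other gave 0 with edgeR (1021 at an unadjusted p under 0.05), and 10 splits are too few for a share under 0.05. Every other split mixes control and knockout libraries, so a real group difference would widen the spread within its groups and lower its calls. Their 0 calls therefore do not measure what chance alone would give. Carry-over of acinar tissue was judged by 30 acinar genes of which no other list holds any, led by Amy2a5 (18801 ± 7133 CPM in control and 20687 ± 12969 in knockout) and Ctrb1 (9483 ± 3417 and 9726 ± 5698). As the source of the group difference it is argued against by similar acinar levels. The list's mean log2 CPM was 8.14 (SD 0.434) in control and 8.10 (SD 0.880) in knockout libraries. With the acinar level as a covariate 98.55% of the 1311 calls outside that list were kept. Levels so alike leave the covariate little room to remove calls, so this share adds little. Growth hormone made from a minigene that MIP-CreER strains can carry is a candidate explanation for part of the changes. The test could have failed, but the response list had a median log2 fold change of 1.02, and Tph1 and Tph2 were both called higher (7 of 11 members rose). Loss of SSBP3 stays open beside it as the biological explanation, since every knockout library carried the transgene and no library with the transgene alone was analysed here.

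Nuclear noncoding RNAs were lower as a set: Meg3, Rian, Mirg and Neat1 fell, while Dlk1, the protein-coding neighbour of Meg3, was not called (log2 fold change 0.41, edgeR adjusted p = 0.725). The shallow libraries alone are argued against by 12 nuclear RNAs outside the Dlk1-Dio3 region and other than Neat1, listed before their values were seen. These 12 hold Firre, named above among the largest decreases. Without the shallow libraries they had a median log2 fold change of -1.08 (SD 1.12), with 10 below 0 and 2 called. Their mean log2 CPM was 2.72 and 2.34 in the deeper control and 1.80 and 0.81 in the deeper knockout libraries. A set of 15 had a median of -1.64 (SD 1.29) without the shallow libraries. It held the same RNAs except Airn, together with Meg3, Rian, Mirg and Neat1, whose fall defined the pattern, so it is not separate evidence. A general loss of imprinting stays open: 22 imprinted genes outside the Dlk1-Dio3 region had a median of -0.30 (SD 0.557), and loss of imprinting can move such genes either way. A smaller share of nuclear RNA in the knockout libraries may account for part of the set. The 12 nuclear RNAs had a median of -1.24 with all 6 libraries (SD 1.13 over the RNAs), with 11 below 0 and 4 called. Of 10000 random lists matched on expression 0 had a median as low, but their members were drawn singly. That count measures spread over unrelated genes, not over the libraries of a group. The 12 were not chosen to leave out imprinted RNAs, and Airn at least is imprinted. They therefore do not separate a smaller nuclear share from a loss of imprinting. The knockout itself stays open and was not tested apart from a smaller nuclear share.

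Lower beta-cell, ER chaperone and oxidative phosphorylation genes could come from fewer beta cells, in which case hormones of other islet cells should be higher. Gcg, Sst, Ppy and Pyy had a mean log2 fold change of -0.57 (SD 0.229 over the 4 genes, and -0.37, SD 0.239, with length and GC offsets). All 4 were below 0, which argues against fewer beta cells as the whole cause, but weakly. The SD over the genes does not measure the spread between libraries. Only Sst of the 4 was called by edgeR, and Gcg and Ppy overlapped between the groups. A trend with transcript length is argued against as the whole cause for oxidative phosphorylation, whose list had a camera adjusted p of 5.17e-07 with length and GC offsets (0.551 with an estimated correlation in place of the preset and no offsets; 3.54e-10 to 0.551 over 18 alternatives), at a median of -0.27 (SD 0.216) against -0.39 (SD 0.235) without them. For the adhesion genes the trend and a change of their own cannot be told apart: with the offsets the adjusted p was 0.0768 (2.66e-05 to 0.466 over 18 alternatives) and the median 0.23 (SD 0.640) against 0.35 (SD 0.612), while 5 of the 6 members called without the offsets were also called with them (7 in all), and why the list's call ended was not tested. A loss shared by all endocrine cells of the islet was not tested. The knockout and the transgene both stay open as explanations for these lists.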
